A study of Mus musculus with 2 samples.

How the data were processed

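The analysis started from the authors' deposited table of raw UMI counts, 17087 genes by 19562 cells, in which every value is a whole number and the ending of each cell name gives its library. According to the submitters' processing notes it was made with Cell Ranger 3.0.1 and Seurat 3.0 on genome build mm10, and the settings are not stated. The libraries were 10x Chromium 3' version 3 libraries loaded at 1000 cells per µl. No reads were realigned. The values show a filter before deposit, with no cell over 2999 genes, a floor near 500 UMIs, and every gene in at least 2 cells, so shares describe cells above that floor and not all droplets. The barcodes of 21 cells occur in both libraries, and 0 cells had no library. Unfiltered droplet counts are not in the table, so empty droplets and free RNA could not be modelled from them.

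Cells with at least 200 genes and at most 20% of counts from the 13 mitochondrially encoded genes were kept, which removed 25.7% of the control cells and 28.5% of the STZ cells for their mitochondrial share. Scrublet, run through scanpy, scored doublets in each library. Its automatic threshold was used in control, where it removed 31 cells (0.58%). In STZ it called 0.0%, under the 0.5% set as the minimum, so the top 628 scores were removed (7.09%, at 0.8% per 1000 cells), and the doublet rule therefore differs between the libraries. Clustering used 2000 variable genes, counts scaled to 10000 per cell, log values scaled within each library, 30 principal components, 15 neighbours and Leiden resolution 1.0.

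Clusters were named from marker genes that were fixed before the data were examined. The rule that applies them was chosen after the clusters had been seen. A marker led a cluster where it was in at least 10% of its cells, at least 1.5-fold over all other cells and at 25% or more of its highest cluster. A cluster took the name of the class with the largest share of its markers leading, with at least 3 of them, and stayed unnamed where its top genes (each in at least 25% of its cells) held more markers of another class or where its UMIs were low and no marker was among them. The names are therefore given with the ending -like. Classes with at least 50 cells in both libraries were compared, and the comparison of gene levels rests on whole clusters.

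Counts of a class were summed over its cells in each library and scaled by all its UMIs (CPM). The log2 ratio is STZ over control, and a count of 0 was set to 3, which makes the ratio a lower bound. Ratios from 1 to 3 counts are given with their interval. Intervals are exact Poisson intervals for sums, exact binomial (Clopper-Pearson) intervals for shares, and intervals from the conditional binomial distribution for ratios. They take UMIs as independent and are too narrow where a few cells hold most UMIs of a gene, which was examined for the named genes after the data had been seen. The median log2 ratio of all genes lay between -0.06 and 0.04 in the 9 classes. No test was made.

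The 35 gene lists, the filters on cells and the alternative settings were chosen before the data were examined, and which lists and classes are described at length was chosen after exploratory values had been seen. A gene of a list counted as measured in a class at a pooled CPM of at least 10 and at least 20 UMIs. The median of a list was placed among 10000 random lists of equal size matched on expression in 20 bins, as a description of these libraries. A gene counts as higher or lower at 1.5-fold. Genes named singly follow a rule. In each class, the 5 genes with the largest ratio in each direction were named among those with at least 50 CPM in the higher library, 50 UMIs in both together, a named symbol, and at 25% or more of the level in their highest class, which was meant to leave out RNA of other cells and let the haemoglobin genes pass in endothelial-like cells. Over all classes, the 10 genes whose smallest ratio was largest were named among those with the same direction in all 9. Of each list described, up to 4 members were named, taken from those with the largest ratios whatever their level in other classes. Exceptions to these rules are marker genes given as measures of other cells' RNA (Gnat1, haemoglobin genes), class markers and metallothioneins summed over the library, and S100a8 and S100a9 of the neutrophil cluster. Some genes that these rules select, and 1 test that needed such a gene, are not reported here. Microglia-like cells, under 50 in control, stand apart from the comparison, and which of the genes selected by the rules are named for them was chosen after the values had been seen. Genes sharing reads with near-identical copies, among them Selenbp1 and Selenbp2, the Hist1 genes, the H2 genes and the haemoglobin genes, depend on how the authors' counting assigned those reads. Gene positions are from the GENCODE annotation on mm10.

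The alternatives were no filter on cells, a filter of at least 500 genes and at most 10% mitochondrial counts, doublets kept, Leiden resolution 0.5 and 2.0, both libraries scaled together, cells called by marker score without clusters, and shares of cells that are not rods. For gene levels they were CPM without mitochondrial, ribosomal and haemoglobin genes, median-of-ratios scaling, the mean of single-cell CPM, cells thinned to 500 UMIs, lists at a minimum of 50 CPM or of 5 UMIs alone, and free RNA taken off. The last takes the summed library as the profile of free RNA, scaled by rod markers, which assigned 22.9% (rod bipolar-like cells, control) to 67.9% (pigment epithelium-like cells, STZ) of a class to it, and so is an upper estimate of that kind. Shares of named cells, the same doublet rule in both libraries, and some settings carried over to gene levels or lists were added after the data had been seen.

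The calculation was tested on simulated counts, drawn from the summed profile of a class at the depth of each library, with 50 genes at each known fold. The draws were Poisson counts without UMIs gathered in single cells. They therefore check the calculation and not how often the intervals hold the true ratio in the real data. In Müller glia-like cells 50 of 50 genes at 2.0-fold fell on the right side of 1.5-fold, and the intervals held the true ratio for 47 to 49 of 50. In endothelial-like cells 44 of 50 did so at 2.0-fold and 50 of 50 at 4.0-fold, and of 3309 unchanged genes 3069 stayed within 1.5-fold, against 3122 of 3122 in Müller glia-like cells. Of 100 random lists of 15 unchanged genes, 2.0% in Müller glia-like and 3.0% in endothelial-like cells fell outside percentiles 2.5 to 97.5.

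The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Random seeds were fixed.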

Results

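Diabetes was induced in male C57BL/6 mice with streptozotocin (STZ), a compound that destroys the insulin-producing cells of the pancreas, and the retina was examined by single-cell RNA sequencing. The STZ mice had received 55 mg/kg into the peritoneum at 3 to 5 weeks of age, counted as diabetic above 300 mg/dL blood glucose, and were killed after 25 weeks of high glucose. The control mice were untreated. Each library was made from 3 pooled retinas, with 1 library per group and no replicates, so each value describes these libraries and each interval, at 95%, covers counting error only. Gene levels are given in CPM, the UMIs of a gene scaled by all UMIs of its class in that library. The question addressed is how the makeup of the retina and the gene expression of its cell classes differed between the STZ and the control library.

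The control library held 7169 cells with a median of 3800 UMIs and 1799 genes per cell, and the STZ library 12393 cells with 2062 UMIs and 1005 genes. In both libraries the cells ended at 2999 genes, and the fewest UMIs in a cell were 501 in control and 499 in STZ. Cells under 800 UMIs made up 5.2% of the control cells and 21.6% of the STZ cells, and the median mitochondrial share was 12.3% and 15.2%. After filtering, 5294 control and 8232 STZ cells were kept. Thinned to 500 UMIs, the kept cells had a median of 365 genes in control and 364 in STZ.

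The kept cells fell into 27 clusters (numbered 0 to 26), which were named by marker genes. Rod-like (Gnat1, Nrl), cone-like (Arr3, Gnat2), rod bipolar-like (Prkca, Trpm1), cone bipolar-like (Otx2, Scgn), amacrine-like (Gad2, Slc6a9), Müller glia-like (Glul, Rlbp1), endothelial-like (Cldn5), pericyte or smooth muscle-like (Rgs5) and pigment epithelium-like (Rpe65) cells each had at least 50 cells in both libraries and were compared. Cluster 0, with 13 control and 1751 STZ cells at a median of 703 UMIs in STZ, matched no class by the naming rule and was left unnamed. Actb, Gnb1, Msi1 and Gnat1 were among its top genes. Rod bipolar-like cells came mostly from cluster 3 in control (846 control and 98 STZ cells) and from cluster 7 in STZ (36 and 685), so their values compare different clusters. Rod-like cells lay in cluster 5 (268 control and 608 STZ) and cluster 6 (380 and 405), and Müller glia-like cells mainly in cluster 2 (646 and 387) and cluster 4 (495 and 432).

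Müller glia-like cells held a smaller share of the STZ library than of the control library, rod-like cells a similar one and endothelial-like cells a larger one. Müller glia-like cells made up 25.1% (24.0 to 26.3) of the kept control cells and 12.6% (11.9 to 13.4) of the kept STZ cells, and 25.2% and 16.1% of the named cells. With at least 500 genes and at most 10% mitochondrial counts required per cell, their log2 ratio of shares was 0.035 instead of -0.99, that of endothelial-like cells 0.70 instead of 1.43 and that of amacrine-like cells 1.98 instead of 1.33. Rod-like cells made up 12.2% and 12.3%, cone-like cells 14.7% and 10.8%, rod bipolar-like cells 17.2% and 9.80%, and cone bipolar-like cells 23.8% and 19.3%. Among named cells alone, rod-like cells were at 12.3% and 15.6%, cone-like cells at 14.7% and 13.7%, and cone bipolar-like cells at 23.8% and 24.6%. Endothelial-like cells were at 1.85% (1.505 to 2.25) and 4.99% (4.53 to 5.49), amacrine-like cells at 1.06% and 2.66%, pigment epithelium-like cells at 1.001% and 2.40%, and pericyte-like cells at 1.83% and 1.82%. Pigment epithelium-like cells were at a log2 ratio of 0.63 instead of 1.26 at resolution 0.5, pericyte-like cells lay between 0.0016 and 1.13 instead of -0.01 in 8 other settings, and rod-like cells were at -0.05 instead of 0.01 with doublets kept. Cluster 0 took 21.3% of the kept STZ cells and 0.246% of the kept control cells, which bears on every share that is not among named cells.

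**Figure D1:**
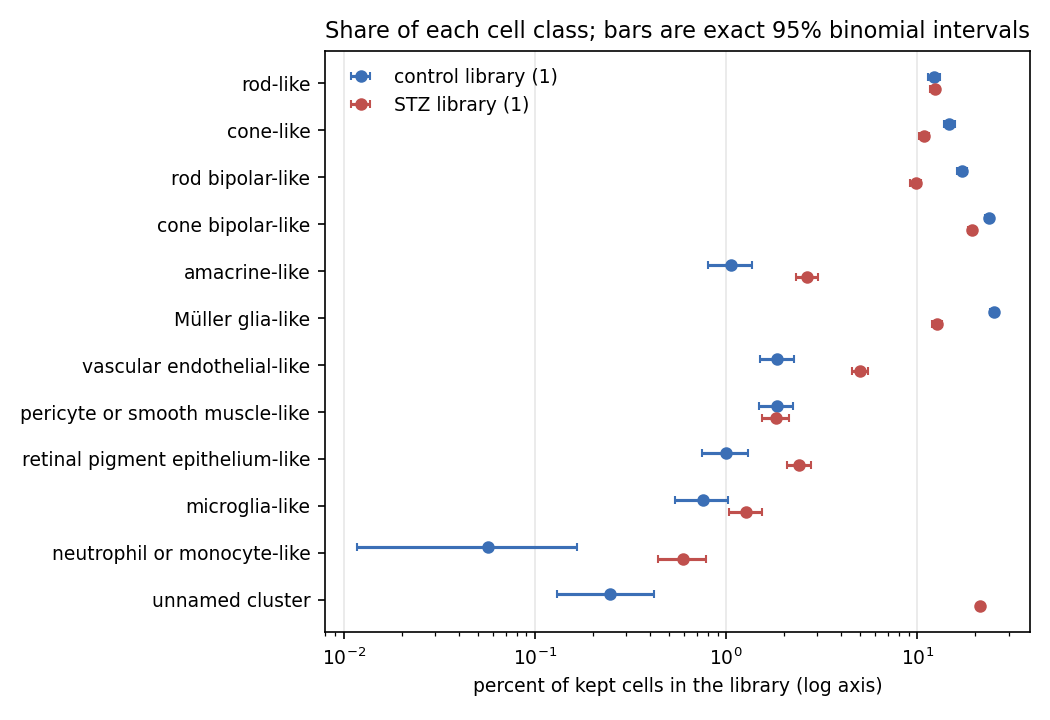
Percent of kept cells (log axis) in each cell class for the control and the STZ library (1 each), with points as shares and bars as exact 95% binomial intervals. Müller glia-like cells were at 25.1% and 12.6%, and the unnamed cluster at 0.246% and 21.3%.

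Both cold-inducible RNA-binding protein genes, Cirbp and Rbm3, were higher in the STZ library in every one of the 9 classes, and the chaperone genes Hspa5 and Calr of the endoplasmic reticulum were lower. Cirbp (chromosome 10, 80165985 to 80172786 on the plus strand), which is induced by mild cooling and stress, was 2.77 to 4.79-fold higher, least in Müller glia-like and most in endothelial-like cells. In rod-like cells Cirbp was at 348 CPM in control and 1029 CPM in STZ, and in cone bipolar-like cells at 345 and 1027 CPM. Rbm3 (chromosome X, 8138975 to 8145880 on the minus strand) was 1.61 to 4.14-fold higher, most in rod-like cells. H3f3b, which encodes the replacement histone H3.3, was 1.20 to 3.06-fold higher, the splicing factor gene Srsf5 1.20 to 2.75-fold and the corepressor gene Sin3b 1.19 to 3.04-fold. Among the genes lower in every class, the chaperone genes Hspa5 (chromosome 2, 34771970 to 34777547 on the plus strand) and Calr were 1.18 to 2.54-fold and 1.35 to 1.87-fold lower, with intervals for Hspa5 that include 1 in endothelial-like (0.962 to 1.59) and pericyte-like cells (0.943 to 1.47). Ldha (chromosome 7, 46841475 to 46855627 on the plus strand), which makes lactate at the end of glycolysis, was 1.22 to 2.49-fold lower, the RNA-binding protein gene Caprin1 1.32 to 2.16-fold and the tubulin gene Tubb4b 1.22 to 2.70-fold. Intervals also included 1 for Caprin1 and Tubb4b in pericyte-like, Caprin1 and Ldha in pigment epithelium-like and Tubb4b in amacrine-like cells, and for Sin3b in endothelial-like, pericyte-like and pigment epithelium-like cells. Cirbp and Rbm3 kept their direction wherever a setting gave a value. Others went the other way: with cells thinned to 500 UMIs Sin3b in amacrine-like (log2 ratio -0.97), pericyte-like (-0.044) and pigment epithelium-like cells (-1.49), Ldha in pigment epithelium-like (1.42, and 0.11 as a mean over cells), Calr in endothelial-like (0.10) and Hspa5 in pericyte-like cells (0.28). So did Tubb4b in amacrine-like (0.15) and H3f3b in endothelial-like cells (-0.91) with free RNA taken off, and Tubb4b in rod bipolar-like (0.098) and Hspa5 in endothelial-like cells (0.022) with the stricter filter. Single values of Caprin1, Ldha, Srsf5, Sin3b and Rbm3 moved by more than 1.5-fold in the same direction, most for Sin3b in endothelial-like cells (1.93 with thinned cells). Of 1394 genes at or above the CPM minimum in every class, 126 went the same way in all 9 (77 higher, 49 lower), and the 9 comparisons share the same libraries and so are not independent.

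**Figure D2:**
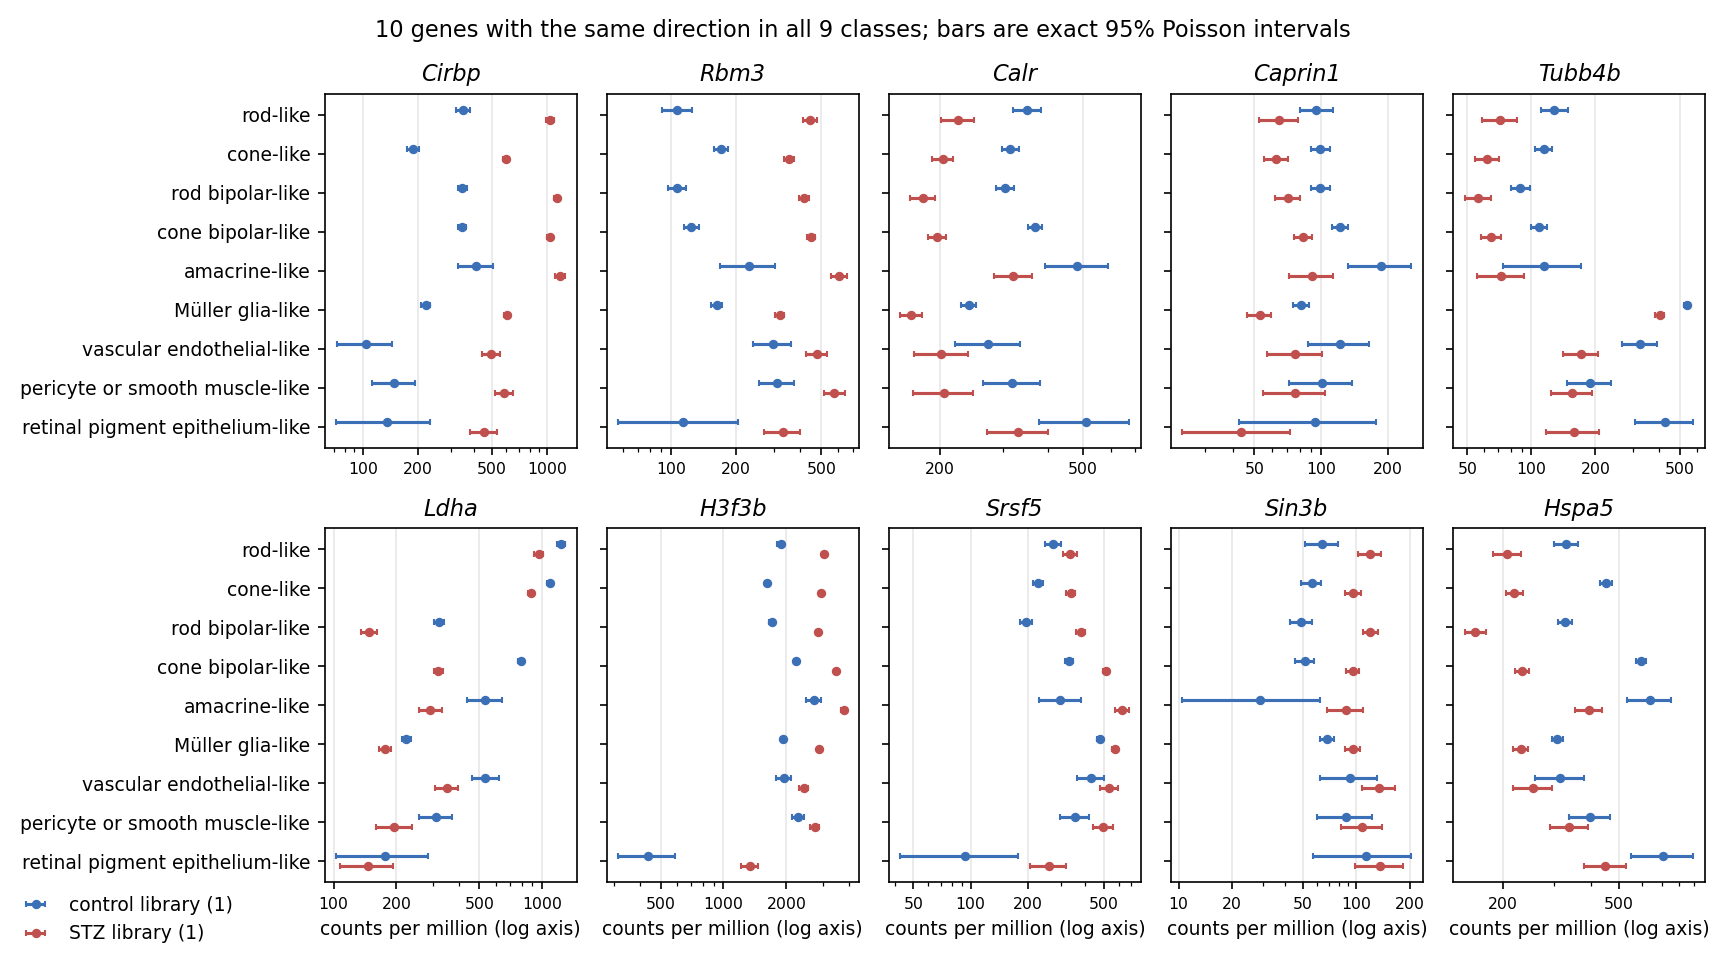
CPM (log axis) of 10 genes in the 9 cell classes of the control and the STZ library (1 each), with points as values and bars as exact 95% Poisson intervals. Cirbp was at 348.5 CPM in control and 1029 in STZ in rod-like cells, and every class shows the same order.

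Genes of the unfolded protein response and of heat shock had median log2 ratios below 0 in every class compared. In the main setting the first were lower in the STZ library most clearly in the photoreceptor and bipolar classes. Those of heat shock were lower most clearly in rod-like, cone-like and rod bipolar-like cells. Metallothionein genes were higher in 8 of the 9 classes. The unfolded protein response list had a median log2 ratio of -0.36 in rod-like cells, -0.38 in cone-like, -0.44 in rod bipolar-like and -0.55 in cone bipolar-like cells. In the same order, other settings gave -0.54 to -0.18, -0.53 to -0.35, -0.51 to -0.13 and -0.66 to -0.50 for this list. In cone bipolar-like cells 9 of its 18 measured genes were at least 1.5-fold lower and 0 higher, a median below all 10000 matched random lists. The cofactor gene Sdf2l1 was 7.18-fold (4.92 to 10.8) lower there, the transcription factor gene Xbp1 2.60-fold (2.29 to 2.95) and the disulfide isomerase gene Pdia6 2.10-fold (1.86 to 2.37). The heat shock list had medians of -0.51 in rod-like, -0.73 in cone-like, -0.54 in rod bipolar-like, -0.27 in cone bipolar-like (2 of 12 genes at least 1.5-fold lower, 1 higher) and -0.47 in pericyte-like cells. In Müller glia-like cells it was at -0.30 (5 of 16 lower, 1 higher) and the unfolded protein response list at -0.23. In microglia-like cells, outside the comparison, these lists were at -0.52 and -0.50. In cone-like cells 9 of 14 heat shock genes were at least 1.5-fold lower. Hsph1, a partner of the main Hsp70 chaperones, was 2.88-fold (1.79 to 4.75) lower in rod-like, 2.03-fold (1.78 to 2.31) in cone-like and 4.29-fold (2.93 to 6.47) in rod bipolar-like cells. Metallothioneins, which bind zinc and copper, had a median of 1.85 in Müller glia-like cells, 1.76 in rod-like, 2.11 in cone-like, 1.74 in pericyte-like and 0.10 in pigment epithelium-like cells. With cells thinned to 500 UMIs that list was under 1.5-fold in 3 of the 9 classes, at 0.45 in amacrine-like (1.44 in the main setting), 0.11 in pericyte-like and -0.36 in pigment epithelium-like cells, and cone-like cells gave no value. In Müller glia-like cells Mt1 (chromosome 8, 94179082 to 94180327 on the plus strand) was at 674 CPM in control and 2424 CPM in STZ, Mt2 (chromosome 8, 94172664 to 94173568 on the plus strand) was 6.18-fold (5.59 to 6.83) higher and Mt3 1.86-fold (1.73 to 1.99). The genes of mitochondrial respiration encoded in the nucleus differed little in neurons, with medians of 0.16 in rod-like, -0.021 in cone-like and 0.032 in cone bipolar-like cells.

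**Figure D3:**
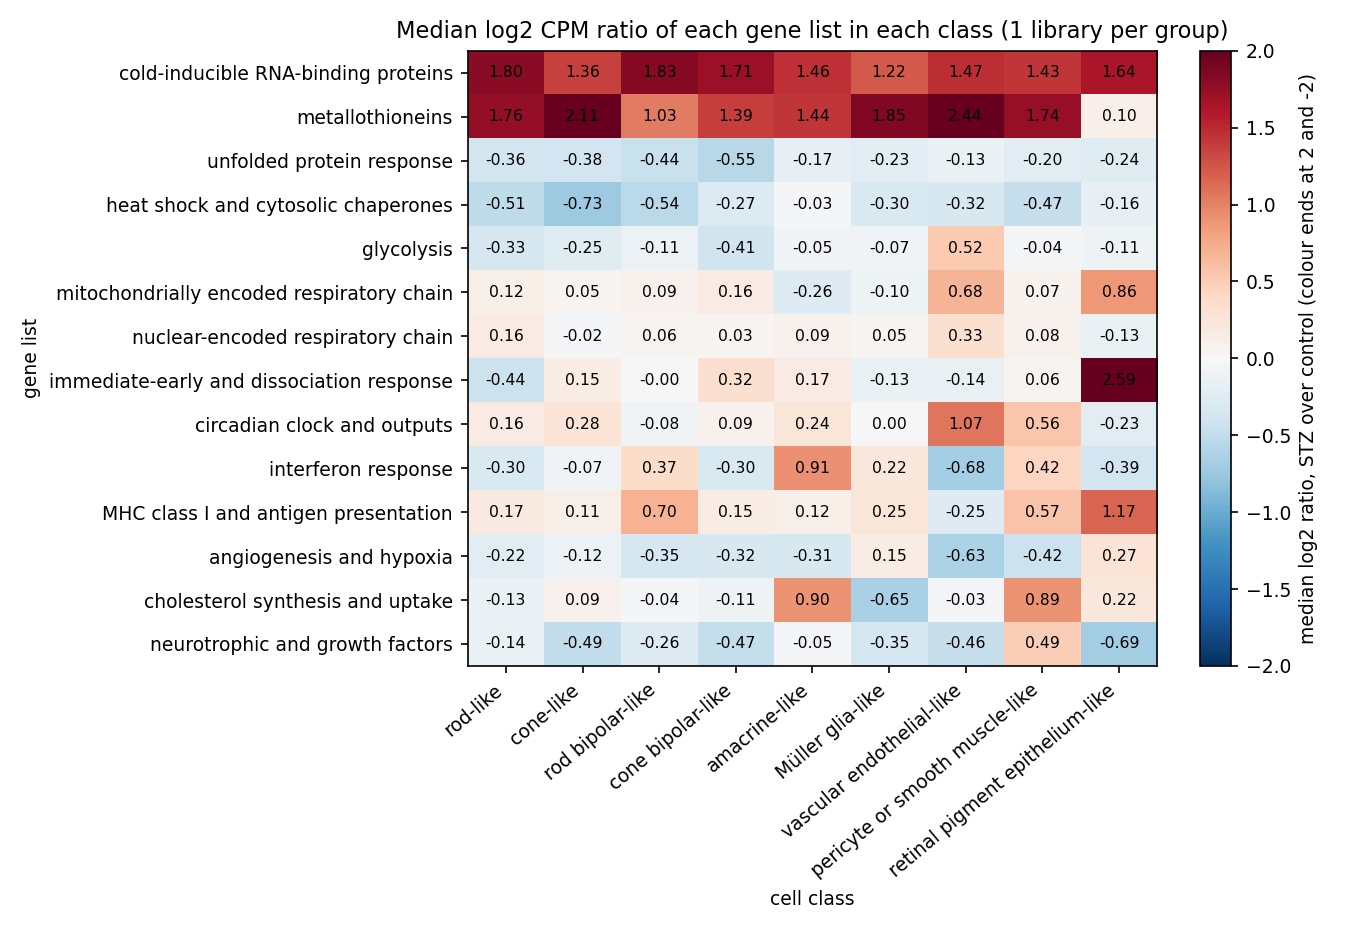
Median log2 ratio of CPM, STZ over control (colour and number), of 14 gene lists (vertical axis) in the 9 cell classes (horizontal axis), with 1 library per group. The cold-inducible list was at 1.81 in rod-like and 1.22 in Müller glia-like cells, and the unfolded protein response list at -0.55 in cone bipolar-like cells.

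In rod-like cells the phototransduction genes were slightly lower in the STZ library and the glycolytic genes more so, while the selenium-binding protein gene Selenbp1 was much higher. The rod phototransduction list had a median log2 ratio of -0.15, with 2 of 21 genes at least 1.5-fold lower (at percentile 0.585 of the matched random lists). Gnat1, the rod transducin gene, was at 6615 CPM in control and 5505 CPM in STZ, the calcium sensor gene Rcvrn at 6466 and 3924 CPM (1.65-fold lower, 1.59 to 1.70), and Guca1a was 1.23-fold (1.19 to 1.27) higher. The outer segment and cilium list had a median of -0.25, with the cilium gene Cep290 1.55-fold (1.35 to 1.80) lower, and the ribbon synapse list -0.10, with the complexin gene Cplx3 1.83-fold (1.46 to 2.29) higher. Glycolysis genes had a median of -0.33 (4 of 20 lower by 1.5-fold, 0 higher), among them Tpi1 at 2.14-fold (1.87 to 2.44), Pfkl at 2.15-fold (1.75 to 2.67) and the lactate exporter gene Slc16a3 at 2.31-fold (1.33 to 4.14) lower. Immediate-early genes had a median of -0.44, with Jun 2.19-fold (1.66 to 2.90) and Fos 2.03-fold (1.44 to 2.87) lower. Selenbp1 (chromosome 3, 94933056 to 94944758 on the plus strand), whose counts can include its near-identical copy Selenbp2, was 4.61-fold (2.71 to 8.28) higher (11.99 and 55.2 CPM), the zinc finger gene Zc3h6 3.09-fold (2.02 to 4.85) and the noncoding RNA gene Sp3os 2.96-fold (2.22 to 3.98). On the lower side were the muscle LIM protein gene Csrp3 (2.71-fold, 1.86 to 4.01), the ciliary motor gene Kif3a (2.41-fold, 1.61 to 3.65), Morn2 (2.28-fold, 1.55 to 3.38), the mitochondrial creatine kinase gene Ckmt1 (2.27-fold, 1.84 to 2.82) and the adenylate kinase gene Ak6 (2.27-fold, 1.49 to 3.52). Genes specific to rods outside the lists had a median log2 ratio of -0.065.

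In cone-like cells Selenbp1 and the dopamine receptor gene Drd4 were higher in the STZ library, the adenylate cyclase gene Adcy1 was lower, and cone phototransduction genes differed little. Selenbp1 had 21 and 321 UMIs in control and STZ, 15.6-fold (10.1 to 25.6) higher. Drd4 (chromosome 7, 141292006 to 141296464 on the plus strand), which encodes the dopamine receptor of photoreceptors, was at 151 CPM in control and 633 CPM in STZ, 4.20-fold (3.85 to 4.59) higher. The motor protein gene Kif4 was 4.91-fold (3.61 to 6.80) higher, the chromatin protein gene Hmgb2 4.06-fold (3.60 to 4.58) and Zc3h6 3.66-fold (2.96 to 4.55). Adcy1 was 2.29-fold (1.88 to 2.80) lower, Morn2 2.15-fold (1.69 to 2.74), Xbp1 2.12-fold (1.72 to 2.62) and Hspa5 2.06-fold (1.90 to 2.23). Cone phototransduction genes had a median log2 ratio of -0.13, with 0 of 13 at least 1.5-fold higher and 0 lower. The short-wave opsin gene Opn1sw was at 6297 and 4927 CPM and the channel gene Cngb3 was 1.47-fold (1.37 to 1.57) lower. Glycolysis genes had a median of -0.25 and included Pfkl, 1.76-fold (1.53 to 2.03) lower. With free RNA taken off, the log2 ratio of Selenbp1 was 6.50 and that of Zc3h6 2.93, with the stricter filter Kif4 was at 1.19 and Xbp1 at -0.35, and with thinned cells Adcy1 at -0.56.

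In both bipolar classes Rbm3 was higher and chaperone genes were lower in the STZ library, and in cone bipolar-like cells glycolysis genes were lower as well. In rod bipolar-like cells Rbm3 was 3.89-fold (3.49 to 4.34) higher, Cirbp 3.23-fold (3.04 to 3.44), Sin3b 2.46-fold (2.07 to 2.92), the motor protein gene Kif22 2.25-fold (1.82 to 2.79) and Selenos, which acts in clearing misfolded proteins, 2.07-fold (1.78 to 2.41). The scaffold gene Magi3 was 2.87-fold (2.37 to 3.51) lower, the LIM cofactor gene Ldb2 2.63-fold (2.27 to 3.05), the Hsp90 partner gene Chordc1 2.48-fold (1.98 to 3.12) and Tmeff1 2.40-fold (1.90 to 3.04). The transporter gene Slc5a8 was also lower (2.60-fold, 2.32 to 2.93), and it is among the genes that set cluster 3 apart. Control cells of this class lay mostly in cluster 3 and STZ cells mostly in another cluster. For every gene of rod bipolar-like cells, a difference between clusters therefore cannot be told apart from one between libraries. The list of ON bipolar signalling had a median log2 ratio of -0.031, with the channel gene Trpm1 at 4589 and 2930 CPM (1.57-fold lower, 1.53 to 1.60), Rgs11 1.55-fold (1.41 to 1.71) lower and Gnb3 1.40-fold (1.35 to 1.45) higher. Genes specific to rod bipolar cells outside the lists had a median of -0.30. In cone bipolar-like cells Rbm3 was 3.60-fold (3.29 to 3.94) higher, the linker histone gene Hist1h1c, a member of a family of near-identical genes, 3.23-fold (2.69 to 3.90), Armcx5 2.54-fold (2.04 to 3.16) and Zc3h6 2.39-fold (2.11 to 2.71). Hspa5 was at 594 CPM in control and 233 CPM in STZ there, 2.54-fold (2.38 to 2.72) lower, Xbp1 2.60-fold (2.29 to 2.95) and Hsph1 2.33-fold (1.87 to 2.93). Of 21 glycolysis genes 7 were at least 1.5-fold lower and 0 higher (median -0.41, below all 10000 matched random lists). Slc16a3 was 2.74-fold (2.27 to 3.34) lower, Ldha 2.49-fold (2.35 to 2.63), Pfkl 2.02-fold (1.85 to 2.21) and the glucose transporter gene Slc2a1 1.75-fold (1.49 to 2.06). Hist1h1c was at a log2 ratio of 2.35 without free RNA.

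In amacrine-like cells genes of cholesterol synthesis were higher in the STZ library, from 56 control and 219 STZ cells. The list of cholesterol synthesis and uptake had a median log2 ratio of 0.90, with 8 of 12 genes at least 1.5-fold higher and 1 lower. Idi1, which makes an isoprenoid precursor, had 3 and 82 UMIs (6.65-fold higher, 2.20 to 32.9). Msmo1 was 3.12-fold (1.37 to 8.77) higher and Hmgcs1 3.09-fold (1.63 to 6.60). Gad1, which makes the transmitter GABA, had 3 and 75 UMIs (6.08-fold higher, 2.004 to 30.2), while the list of GABA and glycine transmission had a median of -0.023. The class marker Gad2 had 11 UMIs over all kept control cells and 69 over all kept STZ cells. The mix of amacrine subtypes in each library was not examined, so a different mix cannot be told apart from different expression. Zfp593 had 1 and 54 UMIs (13.1-fold higher, 2.26 to 529) and Zfand1 2 and 61 UMIs, and Abce1 was 3.98-fold (1.28 to 19.9) higher. With cells thinned to 500 UMIs, Zfp593 (log2 ratio -1.23) and Abce1 (-0.38) went the other way, and Idi1 was at 0.62, Zfand1 at 0.15, Gad1 at 1.35 and Epha8 at -0.97, while Gad1 was at 4.15 with the same doublet rule and Zfp593 at 4.33 as a mean over cells. The ephrin receptor gene Epha8 was 3.83-fold (2.18 to 6.70) lower, Prkcsh 2.83-fold (1.84 to 4.31), Dexi 2.78-fold (1.52 to 5.00), the gap junction gene Gjd2 2.75-fold (1.96 to 3.85) and Chordc1 2.74-fold (1.52 to 4.84). The 131 genes specific to amacrine cells outside the lists had a median of 0.198, with 29 at least 1.5-fold higher and 11 lower. Free RNA was put at 34.2% of the control and 23.3% of the STZ counts.

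In Müller glia-like cells the genes of glial reactivity Lcn2, Gfap and A2m were higher in the STZ library, with interferon-stimulated genes, while cholesterol genes and the growth factor gene Vegfa were lower. Lcn2 (chromosome 2, 32384633 to 32388252 on the minus strand), which encodes an iron-siderophore carrier of inflamed tissue, had 27 and 370 UMIs, or 3.86 CPM in control and 76.8 CPM in STZ, 19.9-fold (13.4 to 30.6) higher. Gfap (chromosome 11, 102887336 to 102900912 on the minus strand), the intermediate filament gene of reactive glia, was 8.45-fold (5.63 to 13.1) higher and the protease inhibitor gene A2m 6.51-fold (4.32 to 10.1). The reactivity list had a median log2 ratio of 0.37, above all 10000 matched random lists, with 3 of 19 genes at least 1.5-fold higher and Id1 1.70-fold (1.58 to 1.82) lower. Over 12 other settings the median of this list lay between 0.14 and 0.52. The list of Müller glia homeostasis had a median of 0.086, with the thyroid hormone enzyme gene Dio2 1.67-fold (1.49 to 1.88) lower and the prostaglandin synthase gene Ptgds 1.52-fold (1.39 to 1.66) higher. Interferon genes had a median of 0.22 (4 of 18 higher by 1.5-fold), with Ifit1 4.24-fold (3.31 to 5.47) and Isg15 1.61-fold (1.27 to 2.03) higher. The cell cycle inhibitor gene Cdkn1a was 8.46-fold (5.68 to 13.01) higher, Arrdc2 3.06-fold (2.55 to 3.69), Zc3h6 3.15-fold (2.61 to 3.81) and the glucose-responsive Txnip 1.93-fold (1.63 to 2.29). Of 17 cholesterol genes 10 were at least 1.5-fold lower and 0 higher (median -0.65, below all 10000 matched random lists), with Idi1 1.86-fold (1.62 to 2.15), Insig1 1.77-fold (1.54 to 2.05) and Cyp51 1.70-fold (1.37 to 2.12) lower. Vegfa (chromosome 17, 46016993 to 46032369 on the minus strand), the main vascular growth factor gene, was at 329.8 CPM in control and 142 CPM in STZ, 2.32-fold (2.13 to 2.53) lower, and its decoy receptor gene Flt1 was 1.64-fold (1.57 to 1.71) higher. The amino acid transporter gene Slc38a2 was 2.30-fold (2.06 to 2.56) lower, Hexim1 2.29-fold (1.96 to 2.68), and the histone genes Hist1h4d and Hist1h2ac, which have near-identical copies, 2.38-fold (1.98 to 2.87) and 2.33-fold (1.92 to 2.85). Gnat1, a rod gene, was at 175 CPM in control and 221 CPM in STZ in these cells, and Müller-specific genes outside the lists had a median of 0.047. With cells thinned to 500 UMIs, Lcn2 was at a log2 ratio of 3.41 and Hist1h2ac at -1.93. The STZ UMIs of Lcn2 lay in 21 cells (118 of 370 in 1 cell), those of Gfap in 19 and those of A2m in 37, so these values are of a few cells of the class.

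In endothelial-like cells the lists of the blood-retina barrier, basement membrane and interferon response were lower in the STZ library, as were most genes specific to endothelium. The barrier list had a median log2 ratio of -0.54, with 8 of 23 genes at least 1.5-fold lower and 2 higher. Mfsd2a (chromosome 4, 122946850 to 122961188 on the minus strand), the lipid transporter gene that keeps transcytosis low, had 115 and 60 UMIs (3.72-fold lower, 2.70 to 5.17), the adhesion gene Icam2 was 2.19-fold (1.62 to 2.95) lower, and Vcam1, which binds leukocytes, was 2.75-fold (1.71 to 4.62) higher. The basement membrane list had a median of -0.70, with the laminin gene Lama4 2.79-fold (1.41 to 5.65) and the perlecan gene Hspg2 2.42-fold (1.49 to 3.99) lower. Interferon genes had a median of -0.68 (13 of 23 lower by 1.5-fold, 0 higher), with Ifi27l2a 6.54-fold (4.21 to 10.4), Stat2 3.69-fold (1.63 to 8.88), Gbp2 3.31-fold (1.76 to 6.42) and Irf1 2.25-fold (1.16 to 4.39) lower. The angiogenesis list had a median of -0.63, with the VEGF coreceptor gene Nrp1 3.68-fold (2.46 to 5.57) lower. Tcf15 (5.17-fold, 3.08 to 8.99), Nr4a2 (4.53-fold, 2.55 to 8.35) and Mndal (4.49-fold, 2.98 to 6.88) were lower too. Genes at 3-fold or more over any other class and outside these lists were lower alike, 57 of 113 by at least 1.5-fold and 2 higher (median -0.59), while 7 photoreceptor genes had a median of 1.15. The rod gene Gnat1 was at 219.7 CPM in control and 487 CPM in STZ, the median depth was 3170 and 949 UMIs, and the median mitochondrial share 5.57% and 12.3%. With free RNA taken off, the barrier list was at 0.13, the matrix list at -0.11, the interferon list at -0.16, Mfsd2a at -1.20 and Mndal at -1.48, and with the stricter filter the barrier list was at -0.18. Lcn2 had 1 and 89 UMIs (45.9-fold higher, 8.03 to 1832) in these cells, and its log2 ratio was 1.96 with thinned cells and 7.09 as a mean over cells, and that of Ifi27l2a -1.96 as a mean over cells. The clock list (median 1.07), the glycolysis list (0.52) and metallothioneins (2.44) were higher, from genes such as Rorb at 16.8% and Aldoc at 16.9% of the level in their highest class, and without free RNA the clock list was at -0.036 (1.98 with a CPM minimum of 50) and the glycolysis list at -1.31, while without a filter on cells metallothioneins were at 3.68. The haemoglobin genes had the largest ratios of all, but of their 4037 UMIs in the STZ endothelial-like cells 4014 lay in 1 droplet, and of the control UMIs of Ifi27l2a 42 of 91 and of Nr4a2 20 of 42 lay in 1 cell each.

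In pericyte-like cells, 97 in control and 150 in STZ, genes of cholesterol synthesis, part of the clock genes and a few interferon genes were higher in the STZ library. The cholesterol list had a median log2 ratio of 0.89, with 9 of 14 genes at least 1.5-fold higher and 0 lower, among them Msmo1 at 4.50-fold (2.30 to 9.83) and Idi1 at 3.44-fold (1.66 to 8.01). Interferon genes had a median of 0.42 (4 of 11 higher by 1.5-fold), with Ifi27l2a 7.91-fold (2.88 to 30.3) and Isg15 2.61-fold (1.10 to 7.13) higher. Of 14 clock genes 7 were at least 1.5-fold higher (median 0.56), with Per2 at 2 and 21 UMIs and Nr1d2 2.58-fold (1.34 to 5.36) higher. The matrix protein gene Spp1 had 4 and 81 UMIs (14.2-fold higher, 5.35 to 53.5), the lipase inhibitor gene Angptl4 2 and 44 UMIs (15.5-fold, 4.04 to 132), and the stress gene Trp53inp1 was 4.16-fold (2.24 to 8.43) higher. Cap2, which acts on actin, was 3.68-fold (2.06 to 6.87) lower, C2cd2 2.62-fold (1.46 to 4.85), the laminin gene Lama5 2.47-fold (1.36 to 4.60), Rbmx 2.32-fold (1.27 to 4.35) and the transcriptional coactivator gene Yap1 2.32-fold (1.27 to 4.35). Hsph1 was 6.75-fold (2.25 to 27.3) and Hspa8 2.11-fold (1.81 to 2.46) lower. The rod gene Gnat1 was at 209 CPM in control and 270.3 CPM in STZ, and pericyte-specific genes outside the lists had a median of -0.08. With thinned cells Spp1 was at a log2 ratio of 1.83, Msmo1 at 0.79, Rbmx at -0.21 and Trp53inp1 at 2.69. Msmo1 was at 3.38, Idi1 at 3.27 and Rbmx at -2.16 with free RNA taken off, and with the stricter filter Spp1 was at 4.53 and Trp53inp1 at 1.36.

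In pigment epithelium-like cells, 53 in control and 198 in STZ, the nuclear noncoding RNA Malat1 and immediate-early genes were higher in the STZ library. Malat1 was at 2057 CPM in control and 11513 CPM in STZ, 5.60-fold (4.85 to 6.49) higher, and all 4 measured nuclear noncoding RNAs were at least 1.5-fold higher (median log2 ratio 1.87). All 10 measured immediate-early genes were higher (median 2.59), with Fos at 2 and 62 UMIs (9.23-fold, 2.45 to 77.9), Junb at 2 and 55 UMIs and Btg2 at 2 and 54 UMIs. Fos stood at 7.89% of its level in the class where it is highest. Of 13 genes encoded in mitochondria 10 were higher (median 0.86), and the median mitochondrial share was 4.75% and 10.6%. Fam169a was 3.52-fold (1.54 to 9.92) higher, the amino acid transporter gene Slc7a8 3.499-fold (1.28 to 13.4), Dnajc8 3.499-fold (1.28 to 13.4) and Ptms 3.08-fold (1.70 to 6.12). The cyclin gene Ccnd1 was 3.36-fold (1.96 to 5.77) lower, the ERK phosphatase gene Dusp6 3.25-fold (1.88 to 5.60), the respiratory gene Cox8b 2.84-fold (2.15 to 3.75), Tubb4b 2.70-fold (1.75 to 4.15) and the insulin signalling gene Irs2 2.67-fold (1.55 to 4.55). Metallothionein gene Mt1 was at 11229 and 12030 CPM, and Mt3 was 2.08-fold (1.76 to 2.45) lower. Gnat1, of rods, was at 519 CPM in control and 414 CPM in STZ, and genes specific to pigment epithelium outside the lists had a median of -0.34. With thinned cells the nuclear noncoding RNAs were at a median of 0.74, Dnajc8 was at a log2 ratio of 0.91 and Cox8b at -2.20, and without a filter on cells the immediate-early genes were at 1.72 and Ptms at 0.93. Genes encoded in mitochondria were at 3.11 and Slc7a8 at 3.57 with free RNA taken off, and as a mean over cells Dusp6 was at -2.45.

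Summed over all kept cells, Cirbp, Rbm3 and the metallothionein genes were higher in the STZ library and Hspa5 was lower. The direction of some class markers turned when the shares of cells were made equal. Cirbp was at 269 CPM in control and 830.1 CPM in STZ, 3.09-fold higher, and 3.05-fold with class shares made equal. Rbm3 was 2.77-fold higher, Mt1 2.82-fold and Mt2 3.58-fold, and Hspa5 was 1.76-fold lower. The endothelial gene Cldn5 was 1.16-fold higher, and 2.92-fold lower with class shares made equal. Shares were made equal by cells, so a class with fewer UMIs per cell in STZ still weighs less there. Endothelial-like cells had a median of 3170 UMIs in control and 949 in STZ, so the 2.92-fold is not a ratio within the class. The bipolar genes Pcp2 and Vsx1 were 1.04-fold and 1.17-fold higher. Both bipolar classes had smaller shares of the kept STZ cells, but the summed CPM weighs UMIs and not cells. Cone bipolar-like cells held 4827642 of 22738505 UMIs in control and 5629725 of 23597103 in STZ, a larger share. Rod bipolar-like cells held 4117853 and 3345573, a smaller one. The pigment epithelium gene Rpe65 was 2.27-fold higher, and 1.24-fold lower with equal shares of cells. The same limit applies there, with a median depth of 1199 UMIs in control and 949.5 in STZ.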

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

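No tests were made of the differences in this part, and the results in it were picked after the values had been seen.

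A gene list stood apart here where its median log2 ratio was 0.3 or more above 0 in one cell class and as far under 0 in another, each at the outer 1% of the matched random lists. Cholesterol synthesis and uptake differed by 1.56 between amacrine-like cells, where Idi1 and Hmgcs1 were higher in the STZ library, and Müller glia-like cells, where Insig1 and Idi1 were lower. Glycolysis differed by 0.93 between endothelial-like and cone bipolar-like cells, where Ldha and Slc16a3 were lower. On the endothelial-like side Aldoc stood at 16.9% of the level in its highest class, and free RNA was put at 36.2% of the control and 67.0% of the STZ counts. With free RNA taken off, the glycolysis median there was -1.31, so its direction was then no longer opposite to that in cone bipolar-like cells. The immediate-early genes differed by 3.02 between pigment epithelium-like cells, where Fos and Junb were higher, and rod-like cells, where Jun and Fos were lower. In the pigment epithelium-like cells Fos stood at 7.89% of the level in its highest class. Interferon response differed by 1.10 between pericyte-like cells, where Ifi27l2a and Isg15 were higher, and endothelial-like cells, where Ifi27l2a and Stat2 were lower and the list median was -0.16 with free RNA taken off.

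Cd74 and H2-Eb1 stood apart because they were outside the classes compared. In microglia-like cells both had 0 UMIs in control, and their log2 ratios with that 0 set to 3 counts were 4.37 for Cd74 (lower limit of the interval 4.05) and 2.94 for H2-Eb1 (lower limit 2.59). Of the 137 and 51 UMIs in STZ 122 and 47 lay in 1 cell, and with cells thinned to 500 UMIs the values were 1.74 and 0.36, so they do not describe the class.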

How the results depend on the processing

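No paired analysis was possible because each group has 1 library, and no test was made. The values here are log2 ratios of STZ over control, or medians of them over a list, and the cause of each movement was not tested. Shares of named cells, the same doublet rule in both libraries, no filter for genes and lists, and, for lists, free RNA taken off, libraries scaled together and doublets kept, and for genes and lists of microglia-like cells resolution 0.5 and 2.0 and marker score, were chosen after the data had been seen.

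In the main setting the shares were 0.01 for rod-like, -0.44 for cone-like, -0.81 for rod bipolar-like, -0.30 for cone bipolar-like, -0.99 for Müller glia-like and 1.43 for endothelial-like cells. The main list medians were -0.33 in rod-like and -0.41 in cone bipolar-like cells for glycolysis, 1.85 for metallothioneins in Müller glia-like cells, and -0.36, -0.38, -0.44 and -0.55 for the unfolded protein response in rod-like, cone-like, rod bipolar-like and cone bipolar-like cells. For heat shock they were -0.51, -0.73 and -0.54 in rod-like, cone-like and rod bipolar-like cells, and for Cirbp and Rbm3 1.81, 1.36, 1.83, 1.71 and 1.22 in rod-like, cone-like, rod bipolar-like, cone bipolar-like and Müller glia-like cells. In endothelial-like cells the interferon list was at -0.68 and the barrier list at -0.54. Müller reactivity was at 0.37, and cholesterol at -0.65 in Müller glia-like and 0.89 in pericyte-like cells.

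With at least 500 genes and at most 10% mitochondrial counts, the shares were 0.20 for rod-like, -0.73 for cone-like, -1.16 for rod bipolar-like, -0.18 for cone bipolar-like, 0.035 for Müller glia-like (the other direction) and 0.70 for endothelial-like cells. The barrier list was at -0.18, and Tubb4b in rod bipolar-like cells at 0.098, the other direction. Amacrine-like and pigment epithelium-like cells were then too few for gene values. With cells called by marker score, the shares were 0.17 for rod-like, -0.066 for cone-like, -0.67 for rod bipolar-like, -0.12 for cone bipolar-like and -0.69 for Müller glia-like cells. Among named cells alone they were 0.35, -0.10, -0.47, 0.043 and -0.65 in the same order, and 1.77 for endothelial-like cells; leaving out the unnamed cluster, mostly STZ cells, raises each by construction. Without a filter the rod bipolar-like share was -0.46. The Müller glia-like share was -0.52 with doublets kept and -0.48 at resolution 2.0.

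With free RNA taken off, heat shock in cone-like cells was at -0.83 and the cold-inducible list in Müller glia-like cells at 0.95. In endothelial-like cells interferon was at -0.16, the barrier list at 0.13, the clock list at -0.036 and nuclear noncoding RNA at -4.79, the last 3 in the other direction. In amacrine-like cells the interferon list was at -0.40 and Tubb4b at 0.15, both in the other direction. There is no such value for rod-like cells, whose genes set the scale. With genes of at least 5 UMIs, crystallins in endothelial-like cells (-0.22) and interferon in amacrine-like cells (-0.45) went the other way.

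With cells thinned to 500 UMIs, the cold-inducible list in cone bipolar-like cells was at 1.57, the barrier list at -0.82 and cholesterol in Müller glia-like cells at -0.82. In amacrine-like cells Zfp593 (-1.23), Abce1 (-0.38) and Sin3b (-0.97) then went the other way, as did Rgs1 in microglia-like cells (-0.64). As a mean over cells the barrier list was at -0.985.

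A value counts as moved outside the interval of its main value (for a list, the interval of the median over its genes), and as reversed where it was at least 1.5-fold in the main setting and then took the other sign. Of 2321 list medians compared, 2183 stayed, 133 moved and 5 reversed. These counts do not tell how many directions held, because the interval of a list spans its genes. Interferon in rod-like cells, at -0.30 in the main setting and 1.08 with the stricter filter, counts as stayed. The barrier list, at 0.13 with free RNA taken off, counts as moved and not as reversed. Of 1719 values of named genes 1551 stayed, 162 moved and 6 reversed, of 107 shares 82, 24 and 1, and of 10 whole-library values, which are of the genes shared by the classes, 8, 2 and 0.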

Other observations

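In microglia-like cells, 40 in control and 104 in STZ and so too few to be compared with the other classes, genes of the resting state were lower in the STZ library. Of 15 measured genes of microglial homeostasis 10 were at least 1.5-fold lower and 0 higher (median log2 ratio -0.70, and -0.93 to -0.57 in other settings), with the purine receptor gene P2ry12 2.09-fold (1.60 to 2.72), Tmem119 2.06-fold (1.57 to 2.70) and Olfml3 2.07-fold (1.53 to 2.81) lower. P2ry12 and Tmem119 each had UMIs in 19 of the 40 control and 31 of the 104 STZ cells, and Olfml3 in 22 and 31. The median depth of the class was 1388.5 UMIs in control and 937 in STZ. A lower level per microglial cell therefore cannot be told apart from a different mix of cells under this name. Maf was 2.92-fold (1.91 to 4.49) lower and Bin2 2.82-fold (1.75 to 4.59). Of the MHC class II genes, Cd74 had 0 and 137 UMIs, H2-Eb1 0 and 51 UMIs and H2-Ab1 5 and 49 UMIs, but 122, 47 and 28 of those in STZ lay in 1 cell, so they do not describe the class. Of the 45 control UMIs of Adamts1, 27 lay in 1 cell. The lists of microglial activation (median -0.084) and inflammatory cytokines (-0.14) had no common direction.

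A neutrophil or monocyte-like cluster held 3 control and 49 STZ cells, with S100a8 at 0 and 717 UMIs and S100a9 at 0 and 978 UMIs. The split from microglia-like cells depends on the clustering. At resolution 0.5 this class held 30 control and 119 STZ cells (log2 ratio of shares 1.35 instead of 3.39) and microglia-like cells 13 and 25, and without a filter on cells or with the stricter filter no cluster took its name. Over the library Hbb-bs had 22 and 6354 UMIs, of which 3686 of those in STZ lay in the unnamed cluster and 2446 in endothelial-like cells, where nearly all haemoglobin UMIs were in 1 droplet. Of the clock genes in cone bipolar-like cells, Per2, Cry1 and Ciart had a median log2 ratio of 0.53 and Nr1d1, Dbp, Tef and Hlf one of -0.34.

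Of the tests that follow, the correlation of the unnamed cluster and, for the barrier list, the removal of cells with haemoglobin were written down before their results were seen. All the others, among them that removal for the interferon list, were chosen after the results had been seen.

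Cirbp and Rbm3 were higher, and the chaperone genes Hspa5 and Calr lower, in every class compared in the main setting. With free RNA taken off, the cold-inducible median in Müller glia-like cells was 0.95, the smallest among the classes with a value. Another scaling is excluded, since the smallest cold-inducible median under either other scaling was 1.18 and the highest unfolded protein response median in photoreceptors and bipolar cells -0.30. Microglia-like cells, outside the comparison, had a cold-inducible median of 1.25, and the gap between the clock groups was 0.86, so a cooler or longer handling of one library, another time of day at collection and STZ diabetes itself cannot be told apart. Retinas of both groups collected in the same hour and held at fixed temperatures, with several mice each, would separate them.

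The unnamed cluster may be free RNA and debris in droplets, but the test made cannot decide this. Its profile correlated better with the sum of all named STZ cells than with the closest class by 0.20 (Spearman coefficient 0.92 against 0.72 over 3275 genes, which are not independent). A mixture of intact cells of several classes with few UMIs would give the same order. The closest class was pigment epithelium-like cells, of whose STZ counts 67.9% were put down to free RNA. Few UMIs as the cause and doublets were not tested. Raw droplet counts would allow a test, and a diabetic loss of RNA from intact cells remains untested.

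The lower barrier, matrix and interferon lists of endothelial-like cells could come from RNA of other cells in their droplets, since endothelial-specific genes outside the lists were lower as well, with a median of -0.59. In its first version, with genes at 10-fold or more over other classes, the test had 14 genes, 4 of them haemoglobin genes, and a median of -0.37, and it was replaced after that was seen. Red blood cells are excluded as the cause for the barrier and interferon lists, whose medians without cells holding a haemoglobin UMI were -0.48 and -0.64, and this was not tested for the matrix list. An effect of STZ diabetes on these genes was not tested apart from this, and sorted endothelial cells from several mice per group would be needed.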
